A study of Mus musculus with 27 samples.

How the data were processed

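Six1 ChIP-on-chip was measured in C2C12 cells at 3 stages with 3 biological replicates each. Per the labels' protocols, chromatin was cross-linked and sheared, and IP and input DNA were amplified by ligation-mediated PCR, labelled with Cy5 (IP) and Cy3 (input) and hybridised together. No dye swap was made. Each array file is the output of Agilent Feature Extraction 10.5.1.1, per the file headers, while the submitters' processing notes name version 10.1. Per the file headers, the processed intensity of each channel was background-subtracted and dye-normalized by a linear method with no lowess term, and probes are placed on mm9. The series tables hold the authors' log2 IP/input values, whose method is not given in the sources used here. Their columns had medians between -0.07 and 0.01 per array, and they correlated with the ratio of the processed intensities at r between 0.82 and 0.91 in the same direction. Direction and centring were thus settled. On the log2 ratio of raw median signals they had slopes between 0.71 and 1.03, with r between 0.78 and 0.97. Their scale was thus near that of this ratio on most arrays, but it was not known exactly.

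Log2 of red over green processed intensity was taken per probe, outlier spots were left out (0.02% of spots), 148 probes on unplaced sequence were dropped, and each array was centred on its median. Windows were centred on each probe with a half-width of 303 bp, set to 1.5 times the median spacing of 202 bp because that exceeded 200 bp, and needed 3 probes. Window means were fitted per design with limma 3.58.1 in R 4.3.3 with a mean per stage, using all 9 replicates, and tested with treat against a fold of 1.5. P-values were adjusted by Benjamini-Hochberg over all windows, at a threshold of 0.05. Called windows less than 500 bp apart were merged, and a region needed 2 windows. Depleted windows past the mirrored test gave the background. Regions of the 3 stages were merged, the mean of all probes in a region was its value, and stage differences were tested with limma's lmFit and eBayes. Without scaling the named regions shared one SE, 0.55 in the merged list and 0.56 in the list over all 9 replicates. Unscaled SEs and p-values therefore rest on a spread pooled over regions and not on a region's own replicates.

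The regions named were, per stage, the 10 with the highest mean among those positive in all 3 replicates, and, per contrast, the 10 largest rises and the 10 largest falls among called regions in which replicates of the stages did not overlap. Chance gives no overlap in 10% of regions for 3 against 3. The rule, the calling of regions and the unscaled stage contrasts were fixed before the data were examined, and other tests were added later. The same rule was applied to the scaled lists and to the list over all 9 replicates, where quantile normalization was chosen after seeing the data. Gene lists, motifs and the parts of the rule that name genes were not run, because no genome or annotation of mm9 was used here. Tables for another assembly were not used for coordinates.

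The pipeline was tested on simulated data made by shifting each replicate's values along the array and adding 5-probe bumps of known log2 height. Bumps of height 3 that were present in all stages were recovered without scaling in 65.1% of myoblast and 60.8% of 24 h cases, and bumps of height 3 in all stages or in myotubes alone in 71.2% of myotube cases. In the list over all 9 replicates the recovery of height 3 was 96.9%. The bumps had one height over all 5 probes. Around the peak probe of the 2831 real regions, the myoblast mean fell from 1.84 to 0.92 and 1.07 at 300 bp on either side. Recovery of real regions of the same peak height may thus be lower. Where simulated gains were all in myotubes, quantile normalization called 38.3% of 2180 unchanged regions between myotubes and myoblasts, and where gains and losses were balanced it called 2.20% of 2177.

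Alternatives were normexp on median signals with an offset of 50 (the files hold median, not mean, signals), loess, scaling to one MAD, quantile normalization, the authors' values, folds of 1 and 2, half-widths of 151.5 bp with 2 probes and of 500 bp, leaving out dim or saturated probes (87.9% of probes kept), other sets of samples or regions, the peak window in place of the region mean, replicate number or scan date as a block, and leaving out each replicate. Probe length correction, which subtracts each array's median at each probe length, was added after seeing the data. The replicates were scanned on 6 dates, of which 3 held replicates of 2 stages.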

Results

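Binding of the homeodomain transcription factor Six1 to chromatin was measured in C2C12 cells, a mouse myoblast line that withdraws from the cell cycle and fuses into multinucleated myotubes when serum is reduced. Chromatin immunoprecipitated with a Six1 antibody was labelled with Cy5, input chromatin was labelled with Cy3, and both were hybridised together, so that each probe gave a ratio of immunoprecipitate (IP) to input. Samples came from 3 stages: growing myoblasts, cells after 24 h in differentiation medium and myotubes after 96 h. Each stage had 3 independent biological replicates, and each replicate was hybridised to 3 array designs that tile different parts of the genome, giving 27 arrays. The designs together held 2903740 placed probes at a median spacing of 202 bp, in 141203 segments covering 648 Mb, and 1929440 windows of at least 3 probes were tested. Positions are on the mouse build mm9, as the file headers give it, and no gene was assigned to a region because no annotation of that build was used here. No IgG arrays were part of the analysis, and the background was taken from windows depleted in the IP to the same degree.

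The 9 replicates differed in the spread of their log2(IP/input) values. The SD over probes was 0.97 ± 0.19 in myoblasts, 1.21 ± 0.46 at 24 h and 1.64 ± 0.09 in myotubes (SD, n = 3 replicates per stage). The IP signal was well above background for 88.7% ± 7.50 of probes in myoblasts, 89.3% ± 5.56 at 24 h and 83.8% ± 6.66 in myotubes (SD, n = 3). The number of arrays limits the precision of every value below. Over all tested windows, replicates of a stage correlated weakly, with r between 0.07 and 0.22. Myoblast and myotube replicates correlated at r between 0.07 and 0.17 over these windows. Across the 2831 regions enriched over all 9 replicates, r within a stage lay between 0.57 and 0.65 for myoblasts, between 0.39 and 0.61 at 24 h and between 0.33 and 0.37 for myotubes. Between myoblasts and myotubes it lay between -0.07 and -0.01 over the same regions. The regions were chosen by their mean over all 9 replicates, which can lower r between stages. These correlations are across regions, which are not independent replicates.

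**Figure D1:**
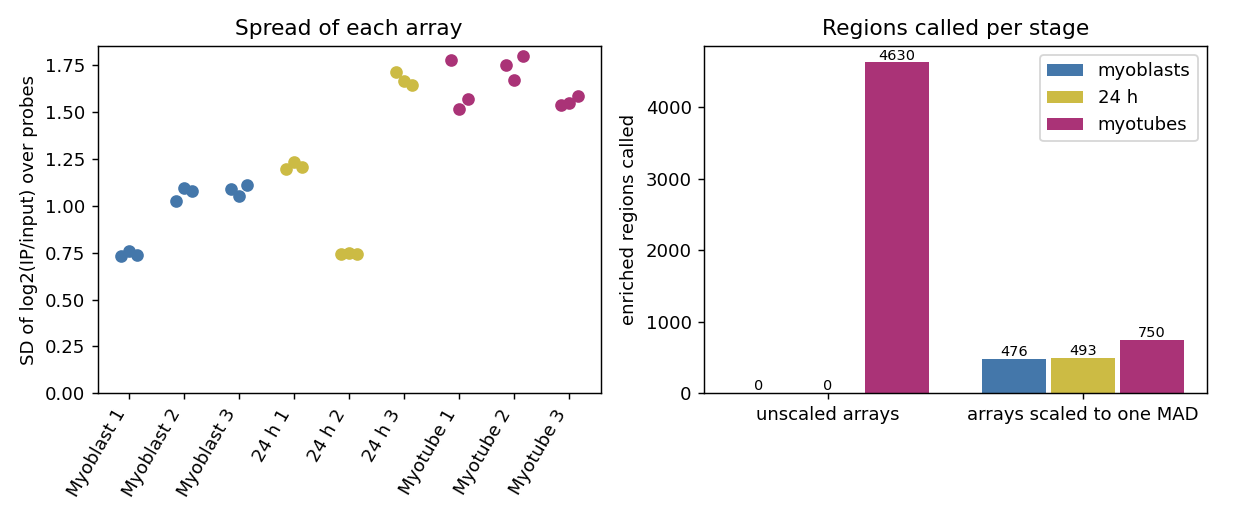
Left, SD of log2(IP/input) over probes for each array, with 3 points per replicate for the 3 designs. Right, number of regions called enriched in each stage without scaling and with each array scaled to one median absolute deviation (MAD). Without scaling 4630 regions were called, all in myotubes, and with scaling 476, 493 and 750 were called in myoblasts, at 24 h and in myotubes.

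The first question was where Six1 lay in each stage. In myotubes, 4630 regions were enriched past 1.5-fold, with a median width of 346 bp and 1929 kb in all. Among these 4630 regions, chromosome 6 from 72423931 to 72424145 had the highest myotube enrichment, with a log2(IP/input) of 5.03 ± 0.59 (SD, n = 3). It was followed by chromosome 14 from 100158799 to 100159053 at 4.74 ± 0.40 and by chromosome 7 from 117258368 to 117258709 at 4.68 ± 0.84. The same 3 regions had means of 2.57 ± 0.69, 2.44 ± 0.86 and 3.59 ± 0.88 in myoblasts. Regions named below from other lists can have other bounds and higher means, and they are not part of this order. In limma's treat test with Benjamini-Hochberg adjustment, 17229 windows passed in myotubes and 845 depleted windows passed the mirrored test, forming 152 regions. Without Myotube replicate 1 the myotube count was 2185, and without Myotube replicate 2 it was 2594. The count was 69 with loess and 822 with the authors' values. Loess was kept out of the planned fit because most ChIP signal is one-sided, and it may remove enrichment. The authors' values had a narrower spread, with an SD of 1.14 against 1.78 for Myotube replicate 1 on design 022328. The same fold of 1.5 was thus a stricter threshold on them. Fits on only the 3 replicates of the stage gave 0 regions in myotubes and 70 in myoblasts. No window passed in myoblasts or at 24 h, where 7640 and 22823 enriched windows had an unadjusted p under 0.05, against 1314 and 7466 depleted ones.

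The myotube regions were then measured in the other stages. In the 4630 myotube regions, the median log2(IP/input) was 0.94 in myoblasts, 1.43 at 24 h and 2.94 in myotubes. The medians per replicate averaged 0.98 ± 0.39, 1.45 ± 0.48 and 2.97 ± 0.25 (SD, n = 3). They overlapped between myoblasts, at 0.56 to 1.33, and 24 h, at 0.90 to 1.79. In the scan date that held both of these stages, the median difference of T24 replicate 2 from Myoblast replicate 2 was -0.46, so the rise in the median at 24 h did not hold within it. All 3 myoblast replicates were above 0 in 74.0% of these regions, against 13.7% of all windows, and all 3 replicates at 24 h in 84.3%, against 15.4%. With each array scaled to one MAD, 476 regions were called in myoblasts, 493 at 24 h and 750 in myotubes, with 1, 0 and 0 depleted regions. In that scaled setting the region on chromosome 9 from 33709418 to 33709661 ranked highest in myoblasts and at 24 h, with unscaled values of 3.89 ± 0.79 and 4.21 ± 0.49. Its scaled means were 5.02 in myoblasts, 4.63 at 24 h and 3.44 in myotubes. On chromosome 1 the region from 138622010 to 138622243 had 3.34 ± 0.78 in myoblasts, 3.62 ± 0.75 at 24 h and 4.27 ± 0.57 in myotubes. Its scaled means went the other way, at 4.41 in myoblasts and 2.99 in myotubes (myotubes minus myoblasts -1.42, limma adjusted p = 0.0168). In simulated data a bump of log2 height 2 was recovered in 0.73% of myoblast cases without scaling and in 65.8% with it. In simulated myotubes scaling lowered recovery, from 19.1% to 2.02% at height 2 and from 71.2% to 27.2% at height 3.

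A list of regions enriched in the mean over all 9 replicates was used to compare stages over one set. It held 2831 regions with 0 depleted regions past a fold of 1.5, against 13511 and 3277 at a fold of 1, and 2753 of the 2831 had a positive value in all 9 replicates. The regions were chosen by their mean over the same 9 replicates, which by itself favours positive values. The list held 1518 regions without Myoblast replicate 2, 1743 without Myoblast replicate 3, 1789 without T24 replicate 1 and 1878 without T24 replicate 3. With loess it held 435, and with the authors' values 769. Regions were ranked at the bounds of this list, which can differ from those of the scaled list. The highest region was chromosome 7 from 117258368 to 117258709, and the second was chromosome 1 from 138622010 to 138622243. The third was chromosome 12 from 9905181 to 9905631, with 3.03 ± 0.67 in myoblasts, 3.93 ± 0.94 at 24 h and 4.18 ± 0.33 in myotubes, and the fourth chromosome 9 from 22992650 to 22992997, with 3.16 ± 0.94, 3.96 ± 0.71 and 4.01 ± 0.43. After quantile normalization myotubes had the lowest of the 3 means at both, with 3.78, 4.20 and 3.23 on chromosome 12 and 3.88, 4.19 and 3.07 on chromosome 9. The difference of myotubes from 24 h was then -0.97 (limma adjusted p = 0.0571) and -1.13 (limma adjusted p = 0.0436). Around the peak probe of these regions the mean log2(IP/input) in myoblasts fell from 1.84 ± 0.56 to 0.43 ± 0.22 at 500 bp, and in myotubes from 3.30 ± 0.24 to 1.33 ± 0.14 (SD, n = 3).

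**Figure D2:**
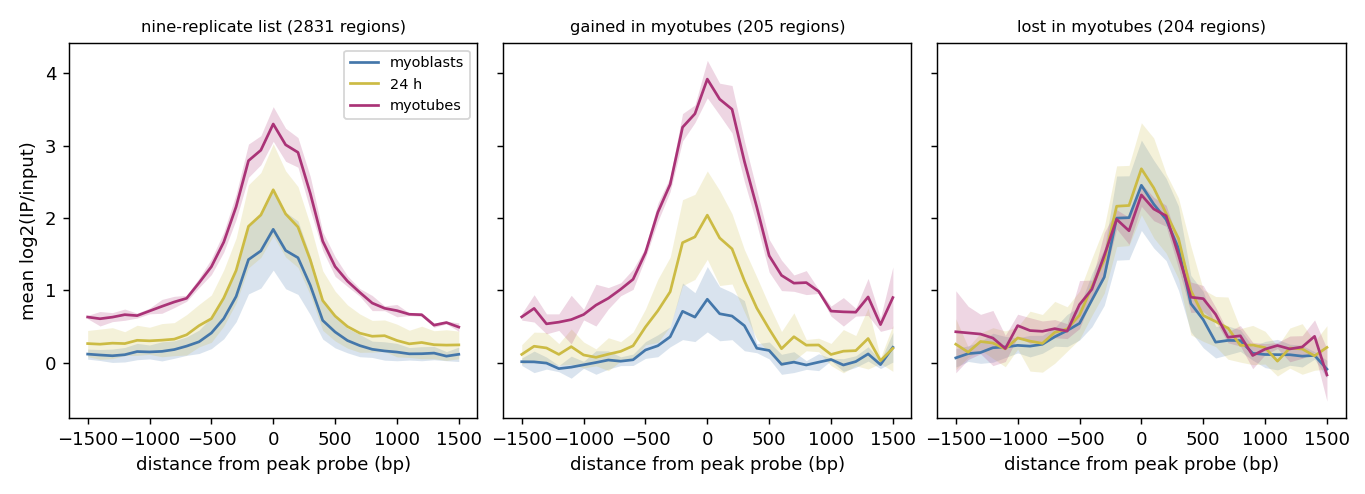
Mean log2(IP/input) against distance from the peak probe in bp, for the 2831 regions enriched over all 9 replicates and for the 205 and 204 of them that were higher or lower in myotubes than in myoblasts after quantile normalization. Lines are stage means and bands are SD over 3 replicates. In the first panel the myotube line peaks at 3.30 and the myoblast line at 1.84.

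Overlap between the stage lists was described next. Without scaling no region was shared by calls, since all 4630 were called in myotubes alone. Counting a second stage by a mean past a fold of 1.5 gave 4029 shared regions, and calling at a fold of 1 gave 653. In the scaled setting the 3 lists merged into 1143 regions, of which 159 were called in all 3 stages. A further 114 were shared by myoblasts and 24 h, 85 by 24 h and myotubes and 57 by myoblasts and myotubes. Calls in a single stage numbered 146 in myoblasts, 134 at 24 h and 448 in myotubes. A call in one stage alone was not a test of a difference: of the 750 regions called in scaled myotubes, 91.1% had positive values in all 3 myoblast replicates. Of the 476 called in scaled myoblasts, 97.3% were positive in all 3 myotube replicates.

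The first 24 h were compared with myoblasts next. Over the 4630 regions, which had been called in myotubes, 7 were higher at 24 h than in myoblasts and 0 were lower (limma, Benjamini-Hochberg adjusted). On these regions the count was 216 with scan date as a random block, 196 higher and 20 lower, 17 with normexp, and 28 with arrays scaled to one MAD, 25 higher and 3 lower. That block had an estimated correlation within dates of -0.67, whereas a shared effect of date would give a positive one. The 216 thus cannot be read as a count corrected for scan date. With regions called anew from each set of values the count was 38 with normexp and 46 of 1143 when scaled, 37 higher and 9 lower. The largest rise was at chromosome 5 from 53400454 to 53400742, from -0.19 ± 0.58 to 2.18 ± 0.39 (log2 difference 2.37, SE 0.55, limma adjusted p = 0.0331). This SE was the same for the other named regions of the list, so it does not measure the spread of this region. The call on chromosome 5 was lost with loess, the authors' values, quantile normalization, replicate number as a block or scan date as a random block. It was also lost on leaving out T24 replicate 1, T24 replicate 3 or any single myoblast replicate. Among the 2831 regions with quantile normalization, 24 passed, 16 higher and 8 lower, against 9 higher and 0 lower without scaling. The 9 were among the 16, and none of the 8 lower regions passed without scaling. On the same regions 2 of the 24 remained called with loess and 7 with the authors' values, and all 24 kept their sign with both. With regions called anew, the count was 0 of 435 with loess and 3 of 769 with the authors' values, and it was 9, 3 and 8 without Myoblast replicate 1, 2 or 3, and 4, 8 and 9 without T24 replicate 1, 2 or 3. The largest of these rises was at chromosome 2 from 48174051 to 48174445, from 0.02 ± 0.45 in myoblasts to 2.78 ± 0.54 at 24 h and 4.69 ± 0.55 in myotubes. Its 24 h difference passed with quantile normalization (2.43, SE 0.35, limma adjusted p = 0.00291) and without it (2.76, limma adjusted p = 0.00264). The largest fall was at chromosome 8 from 80297243 to 80297568, by 1.93 after quantile normalization (SE 0.39, limma adjusted p = 0.0222), and it did not pass without it (limma adjusted p = 0.461). It was also lost with normexp, loess or the authors' values and without Myoblast replicate 1, Myoblast replicate 3, T24 replicate 2 or T24 replicate 3. With scan date as a fixed block 0 regions passed in either list in limma. There 49 of the 4630 had an unadjusted p under 0.05, fewer than the share of 0.05 that no difference would give. The 234 of the 2831 were more than that share. Without T24 replicate 2 the count of 7 became 215. On the same 4630 regions, 2 of the 7 remained called with probe length correction and 0 with loess or the authors' values, and all 7 kept their sign with each. With regions called anew the count was 0 with loess or probe length correction and without Myoblast replicate 3, T24 replicate 1 or T24 replicate 3. It was then 2 and 3 without Myoblast replicate 1 or 2, and 16, 22 and 18 without Myotube replicate 1, 2 or 3.

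Between myoblasts and myotubes the number of regions that differed depended on the regions tested and on the scaling. Of the 4630 regions, 4181 were higher in myotubes and 0 were lower, with a median difference of 1.97 on the log2 scale. These regions had been called in myotubes, whose arrays had the widest spread, and such a choice favours higher calls. With quantile normalization 28 of them passed, 15 higher and 13 lower. On the same regions 1636 passed with loess, 2824 with the authors' values and 1962 with arrays scaled to one MAD, of which 2, 1 and 31 were lower. Calling regions anew left 35 with loess and 616 with the authors' values. Testing all windows in limma gave 0 regions, with 183555 of 1929440 windows at an unadjusted p under 0.05, 111772 higher and 71783 lower. This was more than the share of 0.05 that no difference would give. With arrays scaled to one MAD, 344 of 1143 regions passed, 213 higher and 131 lower. In the 2831 regions, 1802 passed without scaling, 1792 higher and 10 lower, whereas quantile normalization left 409, 205 higher and 204 lower. This list was called on unscaled values, to which myotubes contributed most. Its medians per replicate averaged 1.59 ± 0.52 in myoblasts and 3.06 ± 0.23 in myotubes (SD, n = 3). With arrays scaled to one MAD they averaged 2.00 ± 0.34 and 2.23 ± 0.19, so the unscaled excess of higher calls follows the array spread in part. On the same 2831 regions, 222 of the 409 remained called in the same direction with loess and 259 with the authors' values, and all 409 kept their sign with both. With regions called anew, 34 of 435 passed with loess and 84 of 769 with the authors' values. Calling anew also gave 237, 134 and 136 without Myoblast replicate 1, 2 or 3, 252 without T24 replicate 1 and 263 without Myotube replicate 1. Quantile normalization sets the regions of each replicate to one distribution, so its calls are relative to the other regions. With scan date as a fixed block 666 and 78 regions passed in these lists without scaling and with quantile normalization, and without Myotube replicate 1 the count over the called regions was 1988, without Myotube replicate 2 2349 and without Myoblast replicate 1 2526.

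Regions that rose in both versions included chromosome 2 from 48174051 to 48174445, with a log2 difference of 3.11 after quantile normalization (SE 0.35, limma adjusted p = 4.71e-05). At chromosome 4 from 56759304 to 56759780, the value went from 0.12 ± 0.27 in myoblasts to 1.15 ± 0.25 at 24 h and 4.57 ± 1.03 in myotubes. Chromosome 15 held 2 such regions, at 97945484 to 97945687 and at 75611628 to 75611814, whose myotube means were 4.01 ± 0.35 and 4.95 ± 0.95. All 205 gained regions also passed without scaling, in the same direction. Of the 204 lower regions, 10 also passed without scaling. Without scaling 111 of the 204 were lower in myotubes than in myoblasts, and the others were not. The largest fall was at chromosome 14 from 23642069 to 23642389, from 2.64 ± 0.66 in myoblasts and 2.58 ± 0.47 at 24 h to 0.36 ± 1.19 in myotubes, and it passed without scaling (limma adjusted p = 0.000385). Chromosome 5 from 93466890 to 93467184 went from 2.42 ± 0.71 and 3.07 ± 0.69 to 0.55 ± 0.60 (limma adjusted p = 0.0033 without scaling). For the 204 regions as a set, the unscaled median was 2.24 in myoblasts and 2.08 in myotubes, while that of the 205 gained regions was 0.80 and 3.68. In the 1 scan date that held both stages, the replicates were compared over regions called without them. Of 110 such regions, 99 had the sign of the stage difference.

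**Figure D3:**
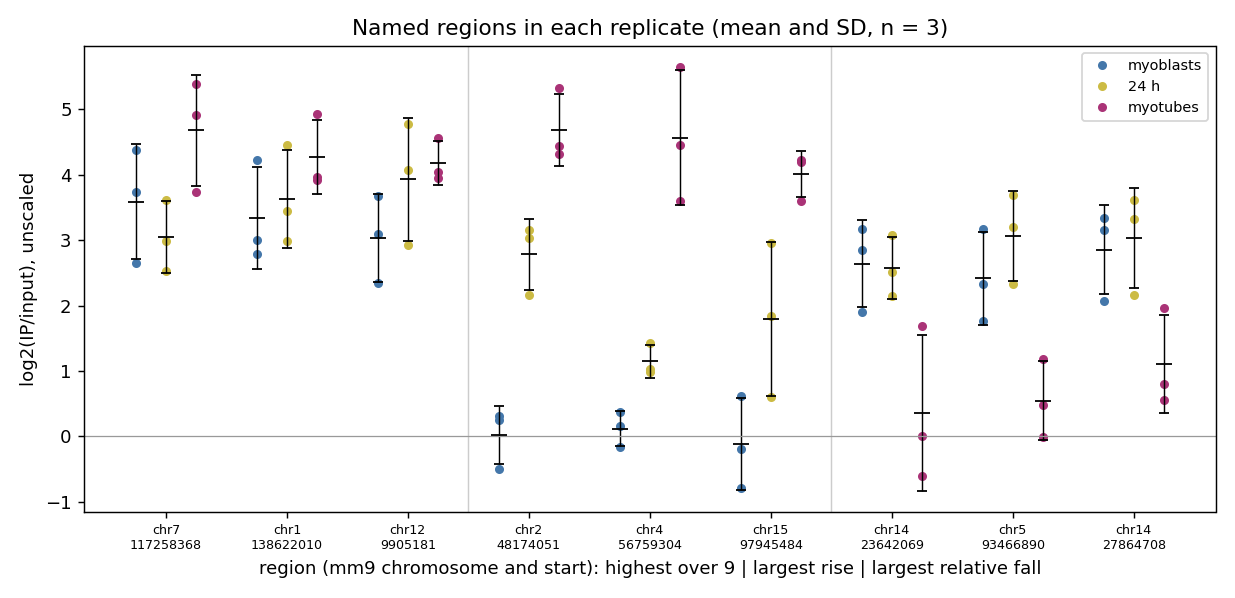
Unscaled log2(IP/input) of 9 named regions in each replicate, coloured by stage, with mean and SD (n = 3). From left to right are the 3 regions highest over all 9 replicates, the 3 largest rises and the 3 largest relative falls in myotubes against myoblasts. At chromosome 14 from 23642069 the myotube mean was 0.36 and the myoblast mean 2.64.

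From 24 h to myotubes, 3203 of the 4630 regions, all called in myotubes, were higher and 0 lower. With quantile normalization 7 of them passed, 5 higher and 2 lower. On the same regions 1109 passed with arrays scaled to one MAD, 1100 higher and 9 lower, 1455 with loess and 2510 with the authors' values. With regions called anew 170 passed when scaled, 101 higher and 69 lower, 41 with loess and 590 with the authors' values. Testing all windows in limma gave 0 regions, with 180626 of 1929440 windows at an unadjusted p under 0.05, again more than a share of 0.05. Calling anew gave 1560 without Myotube replicate 1, 1850 without Myotube replicate 2 and 1707 without T24 replicate 2. In the 2831 regions with quantile normalization 240 passed, 112 higher and 128 lower, against 713 higher and 15 lower without scaling. On the same 2831 regions, 99 of the 240 remained called in the same direction with loess and 114 with the authors' values. Calling anew gave 7 of 435 with loess and 50 of 769 with the authors' values. It gave 156, 92 and 120 without Myoblast replicate 1, 2 or 3, 85, 113 and 149 without T24 replicate 1, 2 or 3, and 146 of 2308 without Myotube replicate 1. With scan date as a fixed block 491 of the 4630 regions passed without scaling and 39 of the 2831 with quantile normalization. The largest rise in the quantile version was at chromosome 9 from 111973683 to 111973962, from 0.55 ± 0.42 at 24 h to 4.01 ± 0.33 in myotubes without scaling, a log2 difference of 3.46, with 0.67 ± 0.54 in myoblasts. Its quantile-normalized difference was 2.70 (SE 0.34, limma adjusted p = 0.000122). Chromosome 16 from 7089353 to 7089685 went from 0.92 ± 0.34 to 4.47 ± 0.43. The largest fall was at chromosome 5 from 93466890 to 93467184 (fell by 3.18 after quantile normalization, SE 0.36, limma adjusted p = 8.08e-05).

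The 24 h values of the regions that differed between myoblasts and myotubes lay nearer to myoblasts for the lower set. Of the 204 lower regions, 173 had a quantile-normalized 24 h mean closer to that of myoblasts. Of the 205 gained regions, 110 were closer to myoblasts and 95 closer to myotubes, with medians of 1.31 in myoblasts, 1.95 at 24 h and 2.81 in myotubes. The regions were chosen on myoblast and myotube values, and such a choice alone can place a separate group between them.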

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

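The tests of array spread, of probe length in the myotube list, of a rise shared by all regions and of depleted regions were chosen after their results were seen, and all tests on the list over all 9 replicates were added to the planned ones. Stage differences in IP over input were tested directly. Over the regions called without scaling, 7 differed between 24 h and myoblasts, 4181 between myotubes and myoblasts and 3203 between myotubes and 24 h. Over the list from all 9 replicates with quantile normalization the counts were 24, 409 and 240. Each contrast has 10 splits of its 6 replicates, too few for a share under 0.05: in each of the 6 cases 1 split, the real one, gave the real count, and the highest of the other splits gave 0.

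The 1st pattern is that regions were called in myotubes alone without scaling. It was not seen in fits on only the 3 replicates of each stage, which gave 70 regions in myoblasts and 0 in myotubes. The myotube count of 4630 was 69 with loess, which may remove one-sided enrichment. It was 822 with the authors' values, whose narrower spread made the same fold a stricter threshold. After scaling each array to one MAD, the lower of the myoblast and 24 h counts was 63.5% of the myotube count, so unequal spread of the arrays may account for the absence of calls in the earlier stages. That share also rests on fewer myotube calls: scaling raised simulated recovery at log2 height 2 in myoblasts from 0.73% to 65.8% and lowered it in myotubes from 19.1% to 2.02%. Scaling gave 476 and 493 regions in myoblasts and at 24 h, against 0 before, but these counts also depend on the myotube arrays. The common MAD was 1.16, against 0.66 to 1.11 on the myoblast arrays, while arrays at 24 h lay on both sides of it. Scaling thus raised myoblast log ratios against a fixed fold. The fit also pooled the spread over replicates of all stages, myotubes included. The rise from 0 is therefore not separate evidence for unequal spread. A trend with probe length is argued against as the whole cause, since 82.2% of the myotube regions overlapped a region called after each array's median at each probe length was subtracted. Base composition was not measured, and 60.04% of probes shared the longest length, so its effect among those stays open. Whether the wider spread of myotube arrays reflects more Six1 on chromatin, a better immunoprecipitation or neither stays open, as no spike-in or IgG array was analysed. The spread was taken over all probes, whereas the 4630 regions covered 1929 kb of 648 Mb tiled, so it need not reflect bound regions. It also varied within a stage: T24 replicate 2 had an SD of 0.75. T24 replicate 3 had 1.67, within the 1.56 to 1.74 of the myotube replicates.

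The 2nd pattern is the set of 409 regions that gained or lost enrichment in myotubes relative to the other regions. The count with regions called anew was 134 without Myoblast replicate 2, 136 without Myoblast replicate 3, 237 without Myoblast replicate 1, 252 without T24 replicate 1 and 263 without Myotube replicate 1. It was then 34 of 435 regions with loess and 84 of 769 with the authors' values. On the same 2831 regions 222 of the 409 remained called with loess and 259 with the authors' values, and 78 regions passed with scan date as a fixed block, which leaves 1 residual degree of freedom. After the subtraction by probe length, 80.4% remained called in the same direction, which argues against a trend with probe length as the whole cause and leaves base composition open. Scan date as the whole cause is argued against by the pair of replicates scanned together: of 110 regions called without that pair, 90% had the same sign within it. A part played by scan date stays open, given the count with the block. Surrogate values at dim spots are argued against because 97.3% of the 401 called regions with at least 2 bright probes remained called. A shift or proportional rise shared by all regions, as from a better immunoprecipitation, stays open. It would keep the regions' order, but r across the 2831 regions was at most -0.0135 between a myoblast and a myotube replicate. Within either stage it was at least 0.33. These regions were chosen by their mean over all 9 replicates, which can lower r between stages, so this r cannot decide. Over all windows r was 0.07 to 0.17 between myoblasts and myotubes, against 0.07 to 0.12 within myoblasts and 0.19 to 0.22 within myotubes. A redistribution of Six1 is a hypothesis, and effects of the IP that differ between regions stay open. Without scaling, 10 of the 204 lower regions passed and 111 had a negative difference. Losses that did not pass without scaling may come from the scaling, since quantile normalization called 38.3% of unchanged regions in simulated data with gains alone.

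The 3rd pattern is the enrichment over all 9 replicates. Dye and probe effects of both signs would give depleted regions too, and past a fold of 1.5 these were 0% of the enriched count. At a fold of 1 there were 3277 depleted and 13511 enriched regions, so such effects stay open for the weaker regions. An effect of one sign alone, such as amplification bias of the IP or nonspecific antibody binding, was not tested, since no dye swap or IgG array was analysed.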

How the results depend on the processing

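Probe length correction, other values on the same regions and all alternatives of the list over all 9 replicates were chosen after seeing the data, and the cause of each change was not tested unless stated. Gene list and motif tests and their alternatives were not run. The size of every count depended on the processing. With normexp, 45 regions were bound at 24 h and 2596 in myotubes, 43 were shared between stages, and 38, 2424 and 1700 differed between 24 h and myoblasts, myotubes and myoblasts, and myotubes and 24 h. With loess, 69 regions were bound in myotubes and the differences numbered 0, 35 and 41. With arrays scaled to one median absolute deviation, 476, 493 and 750 regions were bound in myoblasts, at 24 h and in myotubes, 415 were shared, and 46, 344 and 170 differed. With the authors' values 822 were bound in myotubes, and 10, 616 and 590 differed. Those values had a narrower spread, so the same fold was a stricter threshold on them.

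A fold of 2 left 1492 regions bound in myotubes. A fold of 1 gave 698 at 24 h and 18067 in myotubes, with 7537 depleted in myotubes, and 653 shared. Narrow windows gave 2913 in myotubes, and wide windows gave 1 at 24 h and 1 shared. Without dim and saturated probes, 13 were bound at 24 h and 13 were shared. Fits on only the 3 replicates of the stage gave 70 in myoblasts and 0 in myotubes. Sharing by a mean past a fold of 1.5 in the second stage gave 4029 regions. A stricter overlap of the shorter region left 0.

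For the differences between 24 h and myoblasts, myotubes and myoblasts, and myotubes and 24 h, quantile normalization gave 0, 28 and 7 regions. Regions from the mean over all 9 replicates gave 9, 1802 and 728, or 24, 409 and 240 with quantile normalization. With scan date as a block, which leaves 1 residual degree of freedom, the counts were 0, 666 and 491. As a random block they were 216, 4299 and 3489, with an estimated correlation within dates of -0.67. A shared effect of date would give a positive correlation, so these counts cannot be read as corrected for scan date. Testing all windows gave 0, 0 and 0. For 24 h against myoblasts, the count was 0 with probe length correction, 3 with the peak window and 17 with only the 6 replicates of the 2 stages.

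The replicate block gave 0, 4099 and 2956 regions, and 28, 425 and 260 in the list over all 9 replicates. Same-numbered replicates deviated from their stage means with correlations between -0.03 and 0.06, which show no clear pairing but cannot exclude one. Input was well above background for 90.1%, 96.6% and 99.3% of probes in Myoblast replicates 1, 2 and 3. In T24 replicates 1, 2 and 3 the shares were 91.7%, 96.7% and 99.4%, so these 2 stages may be paired by number.

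The list over all 9 replicates held 1483 regions with normexp, 435 with loess, 769 with the authors' values, 846 at a fold of 2 and 13511 at a fold of 1, with 3277 depleted, against 2831. In it, with regions called anew, the quantile-normalized differences between 24 h and myoblasts, myotubes and myoblasts, and myotubes and 24 h were 21, 212 and 157 with normexp, 0, 34 and 7 with loess, 37, 370 and 207 when scaled, and 3, 84 and 50 with the authors' values. They were 16, 122 and 78 at a fold of 2, 1, 775 and 582 at a fold of 1, 8, 249 and 150 with narrow windows and 7, 364 and 211 with wide windows. With no scaling they were 9, 1802 and 728, and with scan date as a block 0, 78 and 39.

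The counts above with other values are over regions called anew from those values, so list and values changed together. On the same 4630 regions, the differences between 24 h and myoblasts, myotubes and myoblasts, and myotubes and 24 h numbered 17, 4120 and 2595 with normexp, 0, 1636 and 1455 with loess, 28, 1962 and 1109 when scaled, 0, 2824 and 2510 with the authors' values and 2, 4102 and 3153 with probe length correction. On the same 2831 regions they were 23, 371 and 238 with normexp, 2, 245 and 115 with loess, 30, 415 and 273 when scaled, 7, 284 and 125 with the authors' values and 28, 381 and 256 with probe length correction.

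Leaving out each replicate gave 0 to 0 regions in myoblasts, 0 to 13 at 24 h, 2185 to 4979 in myotubes and 0 to 13 shared. The 2185 were without Myotube replicate 1, and without Myotube replicate 2 there were 2594. The differences ranged from 0 to 215, from 1988 to 4590 and from 1560 to 3838. The 215 were without T24 replicate 2, and the 1988 and 1560 without Myotube replicate 1. The list over all 9 replicates ranged from 1518 to 2814, lowest without Myoblast replicate 2, and its differences from 3 to 25, from 134 to 355 and from 85 to 249. Means of named regions, per stage or over all 9 replicates, moved by at least 1 SD in 36 cases with loess, 34 with the authors' values, 27 when scaled, 17 with normexp and 1 with probe length correction. Named differences kept their sign but did not pass in 26 cases with loess, 20 with the authors' values and 8 with probe length correction. Means and differences together stayed the same in 71, 79 and 124 cases. With quantile normalization 18 differences did not pass and 9 did. Differences of myotubes from myoblasts turned sign in places: chromosome 1 from 138622010 had 0.94 unscaled and -1.42 scaled, chromosome 9 from 33709418 had 0.55 and -1.58, and chromosome 7 from 117258368 had 1.09 and, with quantile normalization, -0.65. The share of probes above background in the IP, 79.9% to 96.1% per replicate, limits how low a ratio can be measured.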

Other observations

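The enriched regions over all 9 replicates were placed unevenly. After Benjamini-Hochberg adjustment over 21 chromosomes, 6 chromosomes differed from their share of tested windows by an exact binomial test (two-sided). Chromosome X held 45 regions where 120.1 would follow from its windows (adjusted p = 5.66e-14), and chromosomes 10, 15, 18 and 19 held more, with ratios of 1.27, 1.26, 1.28 and 1.29. Chromosome 2 held fewer, with a ratio of 0.845 (adjusted p = 0.0419). The regions also lay close together: 14.2% were within 10 kb of another, against 2.87% to 6.37% in 1000 random placements on tested windows. Neighbouring regions are not independent, so the chromosome p-values are too small. One hypothesis is that Six1 regions may group around particular genes, which was not tested without an annotation of the build.

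Probes in the 205 gained regions averaged 54.6 ± 4.09 nt (SD over regions) and those in the 204 lower regions 57.1 ± 3.43 nt, a difference of -2.49 nt (permutation test, two-sided, p = 1e-05, the smallest that 100000 draws can give). The mean was 55.1 nt over all 2831 regions and 56.9 nt over all probes. The draws treated regions as independent, which neighbouring regions are not, so this p-value may be too small. Shorter probes on such arrays may mark GC-rich sequence. The log ratio of the shortest minus the longest probes was 0.19 ± 0.14 in myoblasts, 0.59 ± 0.28 at 24 h and 0.90 ± 0.18 in myotubes (SD, n = 3), so part of this difference could follow the array trend, although 80.4% of the calls remained after it was subtracted.

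Input signal was well above background for 23.9% to 43.6% of the 117 chromosome Y probes per replicate, against 80.1% to 99.0% of the 121321 chromosome X probes. Median input signals were 24.2 to 51.6 on Y and 433 to 962 on X. Over all probes, input was well above background for 90.1% to 99.4% per replicate, and median input signals were 790 to 1133 per array. Whether the lower signal on X bears on its low count of enriched regions was not tested.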
